A study of Homo sapiens with 24 samples.

How the data were processed

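Messenger RNA of 24 libraries was measured by sequencing, from PC9 and H1975 cells in 4 treatment groups each (control, almonertinib, paclitaxel, combination) with 3 repeats, taken after 24 h. Per the labels, RNA was extracted with TRIzol and libraries were made with a SMART-RNAseq library kit. The authors deposited a single table of raw read counts per gene, whole numbers without normalisation, for 19702 Ensembl genes. Per the submitters' processing notes HISAT2 2.2.1 and HTSeq were used with GRCh38; the HTSeq version, its parameters, the annotation and the strand that was counted are not stated. Antisense reads may therefore have been counted in some genes. Symbols (19623 genes), positions and transcript lengths came from GENCODE v29 and NCBI gene tables on GRCh38. Every column of the table was used.

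Each line was fitted on its own with its 12 libraries in edgeR 4.0.16 (R 4.3.3): genes with low counts were removed by filterByExpr, which left 12796 genes in PC9 and 12345 in H1975, and library sizes were scaled with TMM factors (0.856 to 1.15). A quasi-likelihood model with a term per group gave two-sided p-values and nearly unshrunk log2 fold changes. The p-values were Benjamini-Hochberg adjusted within each comparison. Genes with an edgeR adjusted p under 0.05 were called. For each line the comparisons were each treatment against the control, the combination against each single drug, and the interaction of the drugs, which is the combination minus both single drugs plus the control. The treatment effects of the lines were compared in a fit of all 24 libraries (13380 genes), as PC9 minus H1975. This made 15 comparisons. The typical biological coefficient of variation between repeats was 0.111 in PC9 and 0.191 in H1975. Counting error was small at this depth for abundant genes, and low raw counts are given where a fold change rests on them.

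Before the data were examined, 34 lists of genes were written from general knowledge (749 entries, of which 745 matched the table), and 30 lists with at least 5 measured members were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The lists not quoted elsewhere are among these 30, and across the 15 comparisons 171 list tests passed an adjusted p of 0.05 at the preset correlation and 17 of those also with an estimated one. Calls among list members were also adjusted over the list alone.

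The genes to be named were fixed by rule before the data were examined. Named in each comparison were the 5 rising and 5 falling called genes with the largest change, given a mean of at least 5 CPM, a protein-coding type and, between treatments, no overlap of the 3 libraries of one group with the 3 of the other. In each list up to 2 rising and 2 falling called members with the smallest p were named, or 1 member as a value where none was called, and members were left out where the list was not described. Some genes that the rule names are not reported here. A further 9 genes, named below, were followed in every comparison. Levels are given as CPM, counts scaled to the library size times its TMM factor.

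Alternatives tried were RLE factors, no filter and a stricter filter on low counts (1 CPM in 3 libraries and a mean of 5 CPM), DESeq2 1.42.0, a term for the repeat number, a fit of all 24 libraries, fits of only the 2 groups compared, and leaving out each library in turn. After the data were seen, fits were added with a trend on transcript length and GC content removed per library (spline with 5 degrees of freedom), without 3 libraries that stood apart, and, in H1975, without almonertinib library 1. The labels do not say that a repeat number marks a shared culture or day. Deviations of libraries with the same number correlated by more than 0.1 in all 3 pairs between PC9 almonertinib and control (0.119, 0.106 and 0.394) and between H1975 combination and control (0.110, 0.169 and 0.345), but not in the other pairs of groups, so the main model has no term for the number. Values with the number as a block are given beside these comparisons where a call of a named gene changed or a count moved by over 1.5 times.

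Tests used simulated data with the same group sizes and spread, 200 changed genes and no length and GC trend. Real rates may differ. Of genes changed 2-fold, edgeR recovered 78.3% in PC9 and 63.5% in H1975 under almonertinib, 75.4% and 14.9% in the interaction and 48.7% in the difference between the lines. Of genes changed 4-fold it recovered 94.1%, 97.2%, 92.9%, 94.9% and 84.7% in the same order. In the H1975 comparison 5.43% of edgeR and 13.7% of DESeq2 calls were false.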

Results

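Messenger RNA was sequenced from PC9 and H1975 cells, established human lung adenocarcinoma lines that carry activating mutations of the growth factor receptor gene EGFR. Cells of each line were kept for 24 h under 4 conditions: control, almonertinib, a covalent inhibitor of mutant EGFR, paclitaxel, a taxane that stabilises microtubules, or both drugs together. PC9 received 2 nM almonertinib or 0.3 nM paclitaxel, and H1975 received 1 nM almonertinib or 1 nM paclitaxel; the doses within the combination are not stated separately in the labels, so the combination groups have no dose here. The doses of the single drugs also differed between the lines, so a difference between lines is a difference between line and dose together. Every condition of every line had 3 libraries, 24 in all. Library totals ran from 14232299 to 24245314 counts, and between 13780 and 14502 genes had at least 1 count in a library.

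The ± of a log2 fold change is a rough standard error that can be too small at low counts. Rose and fell are used of called genes (edgeR adjusted p under 0.05) alone. Because the labels do not say that the 3 libraries of a group came from separate cultures, the p-values measure the spread between these libraries, which may be technical. Lists of genes were compared with all other genes by camera at a preset correlation of 0.01. Lists whose call held with an estimated correlation are named as such, and that adjusted p stands beside the others.

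Almonertinib alone addressed the response to EGFR inhibition. In PC9 it lowered targets of EGFR signalling and raised interferon-stimulated genes. SPRR1B and SPRR1A, which encode precursors of the cornified envelope, fell by −7.69 ± 0.30 and −5.34 ± 0.39 on the log2 scale. KRT6A, a stress keratin, fell by −7.11 ± 0.18, MARCHF4, a ubiquitin ligase, by −5.33 ± 0.25 and TCN1 by −5.21 ± 0.27. The collagenase gene MMP13 rose by 4.60 ± 0.30 (24.3-fold), from 0.578 ± 0.201 to 13.8 ± 4.89 CPM (SD, n = 3 libraries), the keratin gene KRT4 by 4.58 ± 0.19 and TNFSF10, which encodes the death ligand TRAIL, by 4.38 ± 0.23. IFI44L, an interferon-induced gene, rose by 4.20 ± 0.27 and the transcription factor gene BATF2 by 3.95 ± 0.18. The low ends of these folds are few reads, 9 raw counts of SPRR1B over the 3 almonertinib libraries and 27 of MMP13 over the 3 controls. SPRR1A and SPRR1B, like KRT6A and its paralogs, have near-identical stretches, so their shares of reads are uncertain.

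Of 12796 genes tested in PC9, 7253 were called, 3700 higher and 3553 lower, and 2130 of them changed at least 2-fold, 1326 upwards. Among 38 measured genes of the interferon response, 31 rose and 2 fell (31 and 3 adjusted over the list alone), with a median of 1.44. The camera adjusted p was 4.56e-09, and the adjusted p = 0.337 with an estimated correlation. IRF7 rose by 2.64 ± 0.14. The members that fell were ISG20, an exonuclease (−2.17 ± 0.15), and OASL, an antiviral protein (−2.02 ± 0.15), which went from 1583 ± 373 to 389 ± 57.1 CPM. Of 19 genes of antigen presentation, 10 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.00909; 0.376 with an estimated correlation), among them the class I transactivator gene NLRC5 (1.32 ± 0.08) and the peptide transporter gene TAP1 (1.45 ± 0.11).

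Targets of EGFR and MAPK signalling fell in PC9: 22 of 29 fell and none rose (22 and 1 adjusted over the list alone). The median was −0.69, with a camera adjusted p of 7.39e-08, and the call held with an estimated correlation (adjusted p = 0.0449). DUSP6, the phosphatase that inactivates ERK (ENSG00000139318, GRCh38 chromosome 12, 89347232 to 89353271), fell by −1.53 ± 0.13, from 46.9 ± 4.30 to 16.2 ± 2.27 CPM. PHLDA1 fell by −2.75 ± 0.09 and the transcription factor gene KLF4 by −2.77 ± 0.11. Of 12 ERBB receptors and ligands, 8 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0318; 0.313 with an estimated correlation, and 0.129 under a stricter count filter). The EGFR ligand genes AREG (ENSG00000109321, chromosome 4, 74445134 to 74455009) and HBEGF fell by −3.98 ± 0.15 and −3.71 ± 0.15, while the receptor genes ERBB3 and ERBB2 rose by 1.12 ± 0.09 and 0.84 ± 0.09. Of 19 FOXO targets 14 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.00282; 0.313 with an estimated correlation). YPEL3 rose by 1.46 ± 0.13.

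Genes of the G1-S transition and DNA replication fell in PC9 under almonertinib: 24 of 34 fell and 1 rose, also adjusted over the list alone, with a median of −0.82 (camera adjusted p = 1.55e-07; 0.313 with an estimated correlation). The phosphatase gene CDC25A fell by −2.13 ± 0.14 and the DNA methylation gene UHRF1 by −1.42 ± 0.11. Of 27 genes of ribosome biogenesis 18 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.000476; 0.376 with an estimated correlation), with NOP56 at −1.43 ± 0.10 and POLR1G, a subunit of RNA polymerase I, at −1.61 ± 0.17. Of 15 tubulin genes, whose paralogs share reads, 11 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00493; 0.376 with an estimated correlation), with TUBA4A at −1.31 ± 0.12. Of 23 genes of ATF4 and amino acid stress, 18 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 1.75e-05; 0.24 with an estimated correlation). ATF3 fell by −2.87 ± 0.15 and the glutathione-degrading enzyme gene CHAC1 by −1.98 ± 0.12. Of 18 ER chaperones 11 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00554; 0.334 with an estimated correlation).

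Genes of mesenchymal identity and TGF-beta signalling fell in PC9 under almonertinib, 14 of 22 with 3 that rose, also adjusted over the list alone (camera adjusted p = 0.00282; 0.24 with an estimated correlation). FN1, which encodes fibronectin (ENSG00000115414, chromosome 2, 215360440 to 215436172), fell by −3.70 ± 0.16 and the matrix glycoprotein gene TNC by −2.21 ± 0.11. Of 25 NF-kB targets and cytokines 12 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0139; 0.313 with an estimated correlation, and 0.138 under a stricter count filter). IL11 fell by −4.51 ± 0.16 and TNFAIP3, a brake on NF-kB, by −2.54 ± 0.12. Of 22 NRF2 targets 13 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.00282; 0.313 with an estimated correlation), including the glutathione genes GPX2 (1.24 ± 0.12) and GCLC (1.16 ± 0.16). Of 13 mitochondrially encoded genes 11 fell (12 adjusted over the list alone; camera adjusted p = 6.49e-05; 0.373 with an estimated correlation). MT-ND4 fell by −1.51 ± 0.15 and MT-CO1 by −1.43 ± 0.15. The mitochondrial share of all counts was 0.638 ± 0.196% in the PC9 almonertinib libraries and 1.30 ± 0.0792% in the controls (SD, n = 3 libraries). Of 26 genes of the BCL2 family 8 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.644). BMF, a pro-apoptotic BH3-only gene, rose by 1.76 ± 0.10, and PMAIP1, which encodes NOXA, fell by −2.20 ± 0.13.

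**Figure D1:**
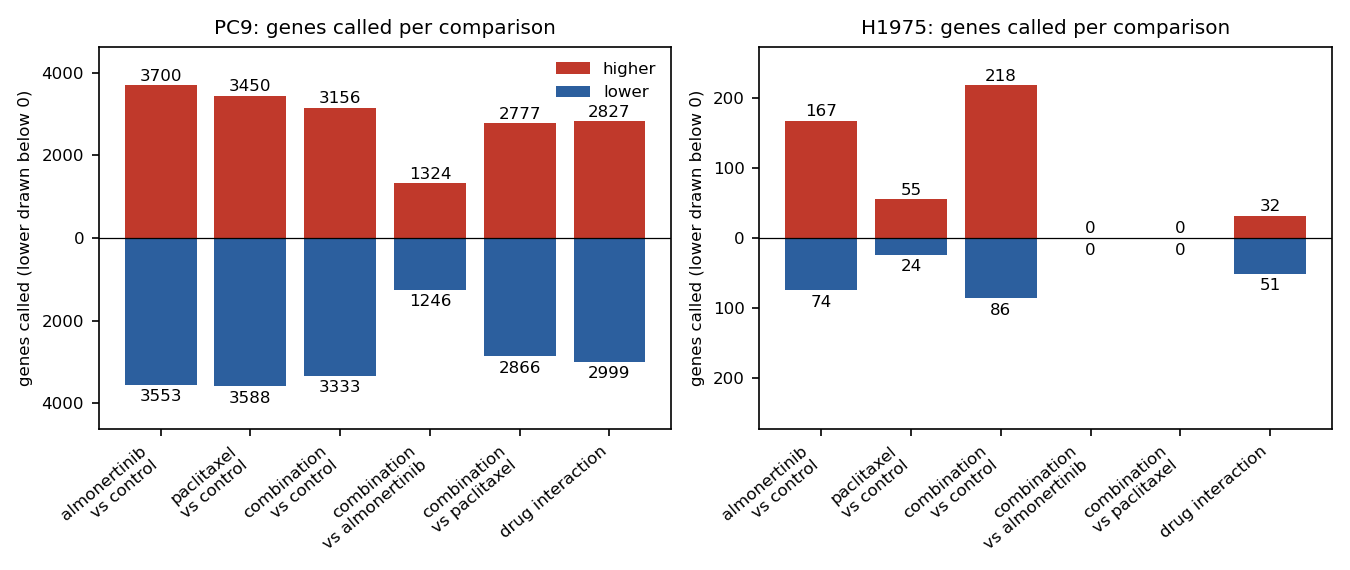
Bars show the genes called by edgeR in each comparison, higher ones (or positive interactions) above 0 and lower ones below, for PC9 (left) and H1975 (right; the scales differ). Counts over the bars run from 1246 to 3700 in PC9 and from 0 to 218 in H1975.

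Paclitaxel alone addressed the response to the microtubule drug. PC9 cells raised interferon-stimulated genes and lowered cholesterol genes. IFI44L rose by 3.89 ± 0.27, MMP13 by 3.76 ± 0.31, and the interferon-induced genes XAF1, TRIM22 and SAMD9L by 3.73 ± 0.28, 3.45 ± 0.27 and 3.22 ± 0.34. SPRR1B fell by −5.27 ± 0.23, SPRR1A by −4.08 ± 0.35, the elastase inhibitor gene PI3 by −3.55 ± 0.20 and KRT6A by −3.29 ± 0.13. BOLA2B, which has a near-identical copy, was at −3.40 ± 0.83, and its call ended without control library 3 (−0.57, edgeR adjusted p = 0.129). Of 7038 genes called 3450 were higher and 3588 lower, and of 1621 that changed at least 2-fold 1245 were higher.

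Interferon genes rose under paclitaxel in PC9, 26 of 38 with 4 that fell (27 and 4 adjusted over the list alone), with a median of 1.48 (camera adjusted p = 1.61e-07; 0.826 with an estimated correlation). OASL and ISG20 fell by −1.54 ± 0.15 and −1.91 ± 0.15. Genes of antigen presentation rose, 11 of 19 with 1 that fell, also adjusted over the list alone (camera adjusted p = 0.0181; 0.826 with an estimated correlation). TAP1 rose by 0.86 ± 0.11 and NLRC5 by 0.63 ± 0.08. Of 24 genes of cholesterol synthesis 19 fell and none rose (20 adjusted over the list alone), with a median of −1.01 (camera adjusted p = 0.000613; 0.826 with an estimated correlation). LSS, the gene of lanosterol synthase, fell by −1.69 ± 0.25. DNA repair genes rose, 15 of 21 with 2 that fell (16 and 2 adjusted over the list alone; camera adjusted p = 0.00204; 0.826 with an estimated correlation). The homologous recombination genes RAD51AP1 and RAD54L rose by 1.75 ± 0.23 and 0.68 ± 0.09, while the checkpoint kinase gene CHEK2 fell by −1.16 ± 0.11.

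FOXO targets rose under paclitaxel in PC9, 15 of 19 with 2 that fell, also adjusted over the list alone (camera adjusted p = 0.000836; 0.826 with an estimated correlation). FBXO32 rose by 1.19 ± 0.13 and ERBB3 by 0.80 ± 0.09, while CITED2 fell by −1.62 ± 0.14. EGFR and MAPK targets fell, 18 of 29 with 3 that rose (19 and 4 adjusted over the list alone; camera adjusted p = 0.000836; 0.428 with an estimated correlation). PHLDA1 fell by −1.16 ± 0.08 and the cytokine gene LIF by −1.34 ± 0.10; KLF5 rose by 0.70 ± 0.11. Among mitotic genes KIF11, the spindle motor, rose by 1.33 ± 0.18 and the centrosome kinase gene NEK2 by 1.01 ± 0.15, while the kinesin gene KIF20A fell by −1.11 ± 0.10 and the cyclin gene CCNB1 by −0.89 ± 0.08. The beta-tubulin genes TUBB6 and TUBB4B fell by −0.77 ± 0.11 and −0.71 ± 0.10. Counts also moved with transcript length beside these groups: the Spearman correlation across genes of a library's deviation with transcript length was 0.294 ± 0.0290 in the paclitaxel and −0.181 ± 0.0535 in the control libraries of PC9 (SD, n = 3 libraries). With a trend on length and GC removed KIF11 stood at 0.62, NEK2 at 0.65, TUBB4B at −0.44, FBXO32 at 0.79 and RAD51AP1 at 1.05, all still called.

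The combination was compared with the control and with each drug. Against the control, PC9 cells raised KRT4 by 4.26 ± 0.19, TNFSF10 by 3.84 ± 0.23, the secreted airway protein gene BPIFB1 by 3.66 ± 0.19, MMP13 by 3.61 ± 0.32 and the acute phase gene SAA1 by 3.54 ± 0.16. SPRR1B fell by −6.26 ± 0.26, KRT6A by −4.73 ± 0.15, MARCHF4 by −4.11 ± 0.22, IL11 by −4.00 ± 0.16 and TCN1 by −3.77 ± 0.24. In all 6489 genes were called, 3156 higher and 3333 lower, and 965 were at least 2-fold higher and 636 at least 2-fold lower. Of 34 genes of the G1-S transition 33 fell and none rose, also adjusted over the list alone, with a median of −1.06 (camera adjusted p = 7.49e-14; 0.262 with an estimated correlation). RRM2, the ribonucleotide reductase subunit, fell by −1.66 ± 0.10 and CDC25A by −2.13 ± 0.14. Genes of G2-M and mitosis fell, 17 of 30 with 2 that rose, also adjusted over the list alone (camera adjusted p = 0.000619; 0.262 with an estimated correlation). The mitotic kinase gene AURKA fell by −0.95 ± 0.09 and CCNB1 by −0.86 ± 0.08. Of 27 genes of ribosome biogenesis 22 fell and none rose, also adjusted over the list alone (camera adjusted p = 1.12e-08; 0.3 with an estimated correlation). NOP56 fell by −1.39 ± 0.10 and BOP1 by −1.43 ± 0.11.

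EGFR and MAPK targets fell under the combination in PC9, 22 of 29 with 2 that rose (23 and 2 adjusted over the list alone), with a median of −0.88 and a camera adjusted p of 4.07e-10. That call held with an estimated correlation (adjusted p = 0.0199). DUSP6 fell by −2.91 ± 0.14, to 6.24 ± 0.471 CPM, PHLDA1 by −3.23 ± 0.09 and the AP-1 gene FOSL1 by −3.22 ± 0.15. AREG and HBEGF fell by −3.72 ± 0.14 and −3.55 ± 0.15. FOXO targets rose, 17 of 19 with 1 that fell, also adjusted over the list alone (camera adjusted p = 3.68e-06; 0.262 with an estimated correlation). FBXO32 rose by 1.78 ± 0.13 and ERBB3 by 1.27 ± 0.09. Interferon genes rose, 28 of 38 with 2 that fell (29 and 2 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 7.41e-08; 0.429 with an estimated correlation), including STAT2 (1.34 ± 0.11) and IRF7 (1.58 ± 0.14). Of 18 ER chaperones 8 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.0133; 0.42 with an estimated correlation). HERPUD1 rose by 0.96 ± 0.09 and HSP90B1 by 1.09 ± 0.15. Of the BCL2 family, BMF rose by 2.33 ± 0.10, while PMAIP1 fell by −1.10 ± 0.12 and BCL2L1, which encodes the anti-apoptotic BCL-XL, by −0.63 ± 0.09. TUBA4A fell by −1.11 ± 0.12.

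**Figure D2:**
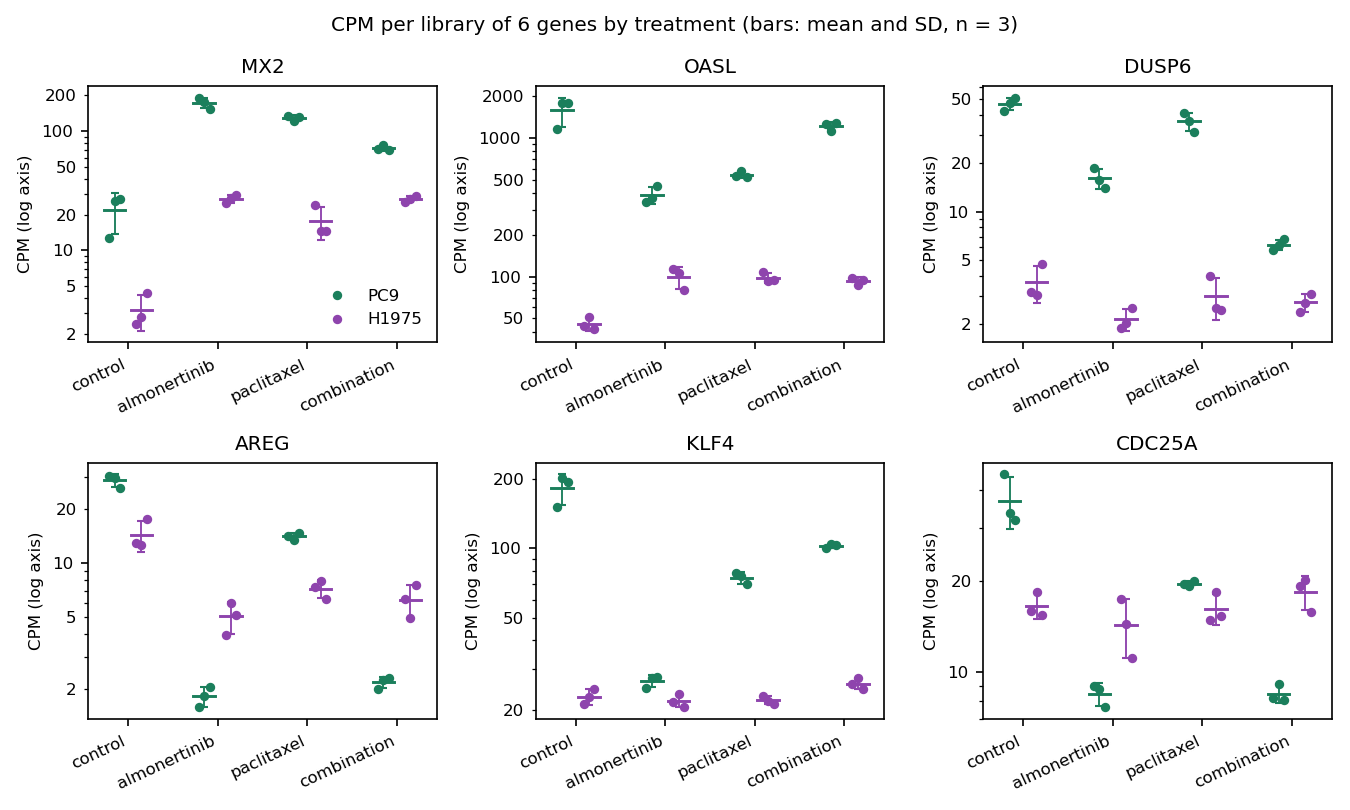
Points show CPM (counts scaled to library size, log axis) of 6 genes in each library of PC9 and H1975 by treatment, with bars for the mean and SD of 3 libraries. In H1975, MX2 had a mean of 3.18 CPM in the controls and 27.2 CPM under almonertinib, and in PC9 DUSP6 fell from 46.9 to 6.24 CPM under the combination.

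Against almonertinib alone, the combination in PC9 raised the chemokine gene CCL5 by 2.87 ± 0.24, the NKG2D ligand gene RAET1L by 2.83 ± 0.18, FN1 by 2.64 ± 0.15, SHISAL1 by 2.57 ± 0.19 and the interferon lambda gene IFNL2, whose paralog shares reads, by 2.52 ± 0.24. DKK1, a Wnt antagonist, fell by −1.70 ± 0.15, the RNA degradation gene PNPT1 by −1.66 ± 0.18, IFI44L by −1.56 ± 0.21, CXCL8 by −1.55 ± 0.26 and BATF2 by −1.55 ± 0.15. ER chaperones rose, 12 of 18 with none that fell (16 adjusted over the list alone), with a median of 0.63 and a camera adjusted p of 6.85e-13; the call held with an estimated correlation (adjusted p = 0.0406). HYOU1 rose by 1.13 ± 0.08 and PDIA4 by 1.16 ± 0.09. Mesenchymal genes rose, 13 of 22 with none that fell, also adjusted over the list alone (camera adjusted p = 1.42e-07), and this call too held with an estimated correlation (adjusted p = 0.0406), with the collagen gene COL5A1 at 1.43 ± 0.11. Interferon genes fell, 25 of 38 with 5 that rose (26 and 5 adjusted over the list alone; camera adjusted p = 7.82e-07; 0.389 with an estimated correlation). IFI35 fell by −1.20 ± 0.12, while OASL and ISG20 rose by 1.65 ± 0.15 and 1.08 ± 0.15. G2-M genes fell, 18 of 30 with none that rose (23 adjusted over the list alone; camera adjusted p = 1.42e-07; 0.0603 with an estimated correlation). The septum protein gene ANLN fell by −1.01 ± 0.15 and the spindle checkpoint gene BUB1B by −0.92 ± 0.16. Genes of ATF4 and amino acid stress rose, 10 of 23 with 1 that fell (12 and 1 adjusted over the list alone; camera adjusted p = 5.51e-06; 0.0833 with an estimated correlation). ATF3 rose by 1.98 ± 0.15 and PPP1R15A by 0.89 ± 0.11.

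Within the EGFR and MAPK targets KLF4 and SPRY2 rose by 1.94 ± 0.11 and 1.28 ± 0.13 between almonertinib and the combination in PC9, while DUSP6 and EPHA2 fell by −1.38 ± 0.14 and −1.01 ± 0.10. Of these 29 targets 3 rose and 11 fell (3 and 12 adjusted over the list alone; camera adjusted p = 0.0105; 0.227 with an estimated correlation). PMAIP1 rose by 1.11 ± 0.13. Mitochondrially encoded genes rose, 12 of 13, also adjusted over the list alone (camera adjusted p = 5.66e-09; 0.276 with an estimated correlation). MT-ND4 rose by 1.18 ± 0.15 and MT-CO1 by 1.07 ± 0.15; their share of all counts was 1.15 ± 0.137% in the combination and 0.638 ± 0.196% in the almonertinib libraries. The comparison called 2570 genes, 1324 higher and 1246 lower. That count was 1274 without combination library 1, 1616 without combination library 3 and 4184 without almonertinib library 3.

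Against paclitaxel alone, the combination in PC9 raised SNPH by 2.66 ± 0.16, the chloride channel gene CLIC3 by 2.52 ± 0.22, KRT4 by 2.42 ± 0.16, the placental phosphatase gene ALPP by 2.42 ± 0.10 and CCL5 by 2.31 ± 0.23. AREG fell by −2.69 ± 0.14, HBEGF by −2.67 ± 0.15, DUSP6 by −2.55 ± 0.14, MARCHF4 by −2.35 ± 0.23 and CXCL8 by −2.34 ± 0.26. All 34 genes of the G1-S transition fell, also adjusted over the list alone, with a median of −1.20 (camera adjusted p = 4.95e-21; 0.183 with an estimated correlation). RRM2 fell by −1.89 ± 0.10 and the replication clamp gene PCNA by −1.52 ± 0.09. DNA repair genes fell, 19 of 21 with 1 that rose, also adjusted over the list alone (camera adjusted p = 1.17e-08; 0.183 with an estimated correlation). RAD54L fell by −1.36 ± 0.09 and FANCI by −1.49 ± 0.14. Ribosome biogenesis genes fell, 25 of 27 with none that rose, also adjusted over the list alone (camera adjusted p = 1.08e-08; 0.257 with an estimated correlation). NOLC1 fell by −1.08 ± 0.11 and NOP56 by −0.88 ± 0.10. Cholesterol synthesis genes rose, 22 of 24 with none that fell, also adjusted over the list alone (camera adjusted p = 1.91e-06; 0.47 with an estimated correlation). LSS rose by 1.93 ± 0.25 and the sterol reductase gene TM7SF2 by 2.03 ± 0.29. ER chaperones rose, 11 of 18 with 1 that fell, also adjusted over the list alone (camera adjusted p = 2.04e-05; 0.197 with an estimated correlation). HERPUD1 rose by 1.05 ± 0.09 and MANF by 1.13 ± 0.10.

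EGFR and MAPK targets were lower in the combination than under paclitaxel in PC9, with 20 of 29 that fell and 2 that rose (21 and 3 adjusted over the list alone; camera adjusted p = 5e-06; 0.122 with an estimated correlation) and PHLDA1 at −2.06 ± 0.09. BMF rose by 1.34 ± 0.09. In the G2-M list 19 of 30 fell and 3 rose (20 and 3 adjusted over the list alone; camera adjusted p = 0.00145; 0.238 with an estimated correlation). The mitotic kinase gene CDK1 fell by −1.37 ± 0.13 and the cyclin gene CCNA2 by −1.13 ± 0.14, while KIF20A rose by 0.60 ± 0.10. In all 5643 genes were called, 2777 higher and 2866 lower.

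The interaction of the drugs asks whether the combination differed from the sum of both single log2 effects; it presumes that the combination held each drug at its single dose, which the labels do not state. In PC9 the interaction was above 0 for genes that each drug had lowered, SPRR1B (6.70 ± 0.60), SPRR1A (5.87 ± 0.55), KRT6A (5.67 ± 0.24), the cytokine gene IL6 (5.42 ± 0.32) and the keratin gene KRT17 (5.39 ± 0.29) leading it. It was below 0 for interferon-stimulated genes each drug had raised, with IFI44L at −5.45 ± 0.34, XAF1 at −4.97 ± 0.35, SAMD9L at −4.69 ± 0.43 and TRIM22 at −4.58 ± 0.35, and for MMP13 at −4.75 ± 0.38. An offset of the 3 controls could alone give either sign. Of 38 interferon genes 28 lay below 0 and 5 above, also adjusted over the list alone, with a median of −2.31 (camera adjusted p = 6.62e-09, or 0.47 with an estimated correlation). IFI35 stood at −2.86 ± 0.17, OASL at 3.19 ± 0.21 and ISG20 at 2.99 ± 0.21. In all 5826 genes were called, 2827 above 0 and 2999 below.

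ER chaperones had an interaction above 0 in PC9, 12 of 18 with 1 below, also adjusted over the list alone (camera adjusted p = 1.08e-05; 0.363 with an estimated correlation). HYOU1 stood at 1.74 ± 0.11 and the stress response transcription factor gene XBP1 at 2.13 ± 0.15. In the mesenchymal list 14 of 22 lay above 0 and 3 below, also adjusted over the list alone (camera adjusted p = 0.00165; 0.363 with an estimated correlation). FN1 stood at 5.09 ± 0.22 and COL5A1 at 2.42 ± 0.16, and KLF4, of the MAPK targets, stood at 3.23 ± 0.15. DNA repair genes lay below 0, 17 of 21 with 2 above, also adjusted over the list alone (camera adjusted p = 0.000429; 0.47 with an estimated correlation). BRCA1 stood at −2.27 ± 0.34 and FANCI at −1.47 ± 0.19; CHEK2 stood at 2.398 ± 0.16. Of 34 G1-S genes 18 lay below 0 and 2 above (19 and 2 adjusted over the list alone; camera adjusted p = 0.00116; 0.587 with an estimated correlation). RRM1 stood at −1.67 ± 0.19 and PCNA at −0.98 ± 0.13.

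**Figure D3:**
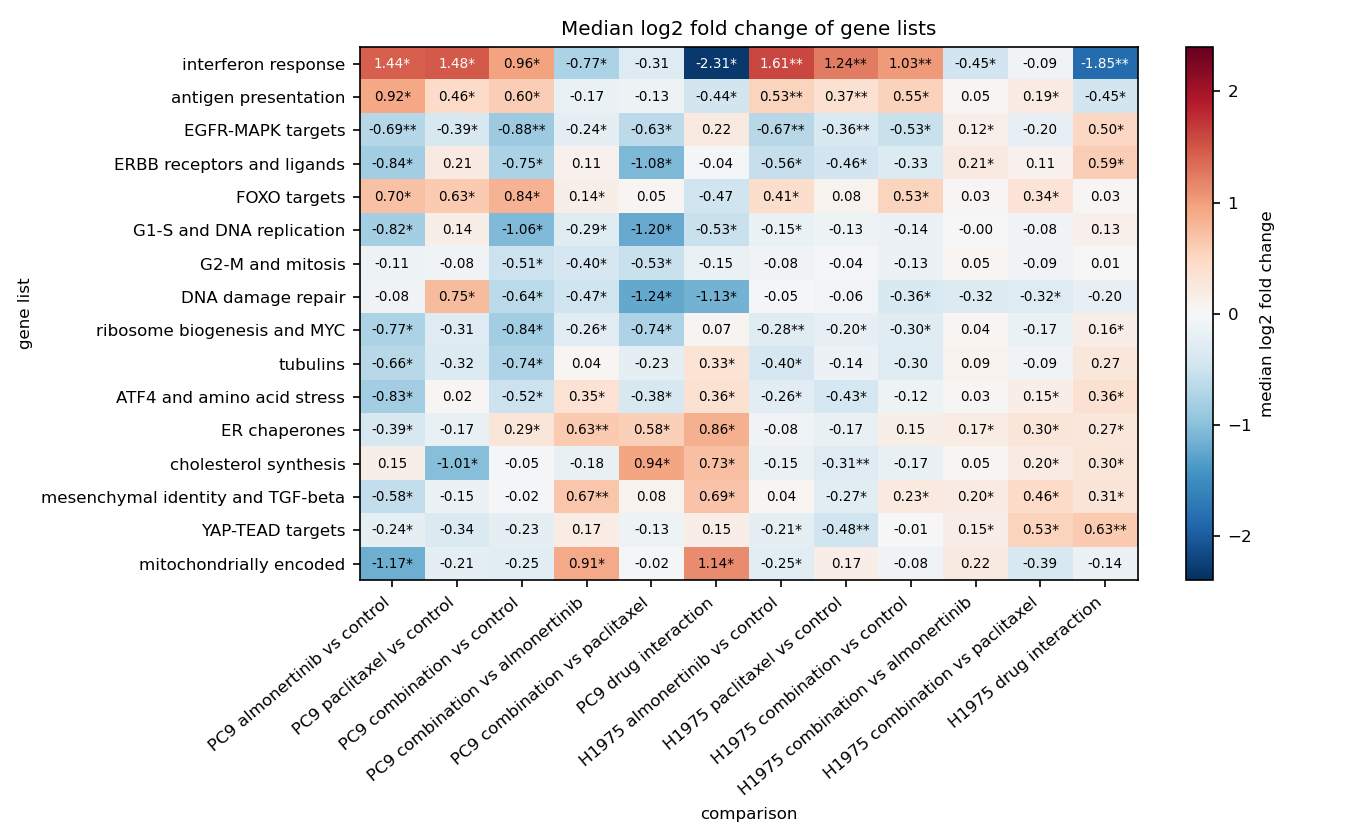
Colour and number give the median log2 fold change (or interaction) of the measured genes of 16 lists (vertical) in 12 comparisons (horizontal); * marks a list called by camera at the preset correlation and ** one called also with an estimated correlation. The interferon row runs from −2.31 (PC9 interaction) to 1.61 (H1975 almonertinib against control).

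H1975 cells under almonertinib raised interferon-stimulated genes and genes of antigen presentation and lowered EGFR targets. CD74, the invariant chain of class II molecules, rose by 3.16 ± 0.30 (edgeR adjusted p = 2.47e-05), the antiviral gene MX2 (ENSG00000183486, chromosome 21, 41361943 to 41409390) by 3.09 ± 0.25, from 3.18 ± 1.07 to 27.2 ± 2.16 CPM (SD, n = 3 libraries). IFI27 rose by 3.002 ± 0.24, OAS2 by 2.86 ± 0.26 and IFI44L by 2.82 ± 0.37. MYEOV fell by −2.04 ± 0.21, the cytokine gene IL24 by −1.65 ± 0.18, the adaptor gene SH2D2A by −1.63 ± 0.27 and AREG by −1.50 ± 0.22. ANGPTL4 was at −1.70 ± 0.42, and its call ended without almonertinib library 2 or 3 or any 1 control and with the repeat number as a block (−1.82 to −1.28, edgeR adjusted p = 0.0619 to 0.163). Of 12345 genes tested 241 were called, 167 higher and 74 lower. Leaving out a library gave 906 calls without almonertinib library 1, with the balance turned to 420 higher and 486 lower, 135 without almonertinib library 3, 115 without control library 1 and 99 without control library 2. With the control and almonertinib libraries alone in the fit the calls of SH2D2A, AREG, DUSP4 and NKX2-1 ended (edgeR adjusted p = 0.0734, 0.0515, 0.0611 and 0.0611).

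Of 37 interferon genes in H1975, 28 rose and none fell under almonertinib (35 adjusted over the list alone), with a median of 1.61 and a camera adjusted p of 3.8e-56. The call held with an estimated correlation (adjusted p = 0.00258). OAS1 rose by 2.14 ± 0.16 and IFI6 by 2.61 ± 0.20. Genes of antigen presentation rose, 9 of 20 with none that fell (14 adjusted over the list alone; camera adjusted p = 2.36e-15), and held with an estimated correlation (adjusted p = 0.0156); HLA-DRA, a class II gene, rose by 3.44 ± 0.43 from 7 raw counts over the 3 controls. Among 27 EGFR and MAPK targets 11 fell and none rose (19 adjusted over the list alone), with a median of −0.67 (camera adjusted p = 3.53e-21), which held with an estimated correlation (adjusted p = 0.011), and DUSP4, an ERK phosphatase gene, fell by −0.93 ± 0.14. PIK3IP1, an inhibitor of PI3 kinase, rose by 2.39 ± 0.32, the lung transcription factor gene NKX2-1 by 0.93 ± 0.14 and the tight junction gene TJP3 by 1.58 ± 0.24. Ribosome biogenesis genes lay lower as a list with no member called of 27, nor over the list alone (median −0.28, camera adjusted p = 4.98e-06; 0.0278 with an estimated correlation).

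Paclitaxel in H1975 raised the same kind of genes. CD74 rose by 2.94 ± 0.30, IFI27 by 2.64 ± 0.24, MX2 by 2.47 ± 0.25, IFI44L by 2.42 ± 0.36 and OAS2 by 2.41 ± 0.25, with HLA-DRA at 3.35 ± 0.44 from its few control reads. The protease gene KLK6 fell by −1.69 ± 0.20, the keratin gene KRT81 by −1.41 ± 0.18, IL24 by −1.40 ± 0.18, the matricellular gene CCN1 by −1.37 ± 0.17 and the carboxypeptidase gene CPA4 by −1.18 ± 0.18. Interferon genes rose, 17 of 37 with none that fell (34 adjusted over the list alone; median 1.24, camera adjusted p = 2.56e-58), and held with an estimated correlation (adjusted p = 0.00225), IFI6 at 2.29 ± 0.20 and OAS1 at 1.81 ± 0.16. Genes of antigen presentation, CD74 and HLA-DRA among them, rose, 4 of 20 with none that fell (8 adjusted over the list alone; camera adjusted p = 4.97e-11), and held with an estimated correlation (adjusted p = 0.0303). YAP-TEAD targets were lower, 2 of 21 with none that rose (7 adjusted over the list alone; camera adjusted p = 4.78e-12), and held with an estimated correlation (adjusted p = 0.0058), with CCN1 and CCN2 (−1.87 ± 0.30) the called members. Of 27 MAPK targets 1 fell (9 adjusted over the list alone; median −0.36; camera adjusted p = 2.07e-11; 0.0303 with an estimated correlation). Cholesterol genes lay lower as a list, with none of 24 called (6 fell adjusted over the list alone; median −0.31; camera adjusted p = 1.12e-05; 0.0303 with an estimated correlation). SQLE stood at −0.73 ± 0.19 (edgeR adjusted p = 0.118). In all 79 genes were called, 55 higher and 24 lower (97 and 75 by DESeq2, and turned to 210 and 265 with the length and GC trend removed). The count was 33, 34 and 48 without control library 1, 2 and 3, and 39 without paclitaxel library 2 or library 3; paclitaxel library 1 had a mitochondrial share of 2.50%, above the 0.977% of the lowest paclitaxel library.

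Under the combination in H1975, CD74 rose over the control by 3.29 ± 0.30, MX2 by 3.09 ± 0.25 and OAS2 by 2.93 ± 0.26. MX1 rose by 2.77 ± 0.24, the interferon-induced kinase gene CMPK2 by 2.45 ± 0.23 and HLA-DRA by 3.62 ± 0.43. MYEOV fell by −2.08 ± 0.21, SH2D2A by −1.62 ± 0.27, the immediate early gene EGR1 by −1.38 ± 0.23 and KLK6 by −1.35 ± 0.20. Interferon genes rose, 19 of 37 with none that fell (27 adjusted over the list alone; median 1.03, camera adjusted p = 1.82e-28), and held with an estimated correlation (adjusted p = 0.0261), OAS1 at 2.04 ± 0.16. Of 20 genes of antigen presentation 6 rose (15 and 1 that fell adjusted over the list alone; camera adjusted p = 1.77e-11; 0.0543 with an estimated correlation). Of 27 MAPK targets 9 fell (16 adjusted over the list alone; camera adjusted p = 1.15e-09; 0.0799 with an estimated correlation). DUSP4 fell by −1.03 ± 0.14. NKX2-1 rose by 1.13 ± 0.14, PIK3IP1 by 1.99 ± 0.33 and the matrix gene TGFBI by 1.13 ± 0.17.

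Some of these calls ended with 1 library fewer while the folds stayed about as large. IGFBP2 was at −1.31 ± 0.24, called in the combination but not without any 1 of the 3 combination libraries or control library 1 (−1.37 to −1.21, edgeR adjusted p = 0.0517 to 0.0813). ERBB3 (0.81 ± 0.16) and BMF (0.97 ± 0.22) lost their calls without any 1 combination library or control library 1 or 2, at 0.71 to 0.81 and 0.87 to 1.04 (edgeR adjusted p = 0.057 to 0.118 and 0.0921 to 0.2). The combination called 304 genes, 218 higher and 86 lower, and 202 with the repeat number as a block. The excess of higher genes turned with only the 2 groups in the fit (919 higher and 998 lower), with the length and GC trend removed (787 and 968) and without 3 libraries that stood apart (1119 and 1320). Without combination library 1, 2 or 3 it called 111, 73 and 78, and without control library 1 or 2 it called 64 and 84.

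In H1975 no gene was called by edgeR between the combination and almonertinib, where 1230 had an unadjusted p under 0.05 and DESeq2 called 41, nor between the combination and paclitaxel, where 1704 had an unadjusted p under 0.05 and DESeq2 called 481. Interferon genes lay lower in the combination than under almonertinib as a list, with no member of 37 called, nor over the list alone (median −0.45, camera adjusted p = 3.83e-06; 0.332 with an estimated correlation). ISG15 stood at −0.72 ± 0.23 (edgeR adjusted p = 0.499). The cholesterol export gene NPC1 was at 0.77 ± 0.16 and VEGFA at 0.69 ± 0.17 in that comparison (both edgeR adjusted p = 0.499). Against paclitaxel, YAP-TEAD targets lay higher with none of 21 called (9 rose adjusted over the list alone; camera adjusted p = 2.26e-06; 0.0847 with an estimated correlation). CCN1 stood at 0.71 ± 0.17 (edgeR adjusted p = 0.0858). Mesenchymal genes lay higher with none of 22 called (8 rose adjusted over the list alone; camera adjusted p = 2.26e-06; 0.147 with an estimated correlation). THBS1 stood at 1.16 ± 0.20 (edgeR adjusted p = 0.0506), and NPC1 and IGF2R stood at 1.07 ± 0.16 and 1.09 ± 0.21 (edgeR adjusted p = 0.0506 and 0.0625). The log2 fold changes against paclitaxel correlated with transcript length (Spearman's rho 0.330), and deviations of paclitaxel libraries 1, 2 and 3 ran with length at 0.341, −0.467 and −0.473, against 0.174 to 0.334 in the combination libraries. Without almonertinib library 1 the first comparison called 1101 genes, 178 higher and 923 lower, and without paclitaxel library 1 the other called 424, 328 higher and 96 lower.

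The interaction in H1975 was below 0 for interferon-stimulated and class II genes, IFI27 at −3.26 ± 0.33, IFI44L at −3.14 ± 0.49, XAF1 at −2.999 ± 0.48, CD74 at −2.82 ± 0.39, IFI6 at −2.74 ± 0.27 and HLA-DRA at −3.17 ± 0.54. It was above 0 for IL24 (1.80 ± 0.25), KLK6 (1.76 ± 0.29), CCN1 (1.54 ± 0.24), CPA4 (1.501 ± 0.25), the glucose transporter gene SLC2A1 (1.36 ± 0.21) and NPC1 (1.398 ± 0.23). Of 37 interferon genes 19 lay below 0 and none above (33 adjusted over the list alone), with a median of −1.85 (camera adjusted p = 2.97e-44), and the call held with an estimated correlation (adjusted p = 0.00597). Low controls would alone put them below 0. YAP-TEAD targets lay above 0, 2 of 21 called (5 adjusted over the list alone; camera adjusted p = 1.05e-10), and held with an estimated correlation (adjusted p = 0.00864). Their member CCN2 stood at 2.27 ± 0.42, but its call ended without almonertinib library 3, control library 2, paclitaxel library 2 or 3 or any 1 combination library (2.13 to 2.42, edgeR adjusted p = 0.0542 to 0.0881). The call of the hexokinase gene HK2 (1.55 ± 0.28) ended without almonertinib library 3, combination library 2 or 3 or paclitaxel library 2 or 3 (1.43 to 1.58, edgeR adjusted p = 0.0537 to 0.0763). In all 83 genes were called, 32 above 0 and 51 below, a balance that turned by DESeq2 (168 above and 80 below). The count was 596 without almonertinib library 1 and 43 without almonertinib library 3; without combination library 1, 2 or 3 it was 32, 31 and 33, without control library 1, 2 or 3 it was 41, 37 and 50, and without paclitaxel library 2 or 3 it was 33 and 29.

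The responses of the lines were tested against each other in one fit of all 24 libraries, as the response in PC9 minus that in H1975. Under almonertinib the difference was called for 2216 of 13380 genes, 740 above 0 and 1476 below, an excess below that ended with the length and GC trend removed (1986 above and 1917 below). It was −3.77 ± 0.30 for FN1, −4.87 ± 0.32 for IL6, −3.85 ± 0.24 for HBEGF, −2.50 ± 0.25 for AREG, −2.73 ± 0.16 for KLF4 and −2.17 ± 0.15 for PHLDA1. The interferon gene IFITM2, whose paralogs share reads, stood at 3.22 ± 0.31, while OASL, which fell in PC9, stood at −3.17 ± 0.24. G1-S genes differed, 18 of 34 below 0 with none above (19 adjusted over the list alone; camera adjusted p = 2.59e-06; 0.116 with an estimated correlation). CDC25A stood at −1.93 ± 0.24 and the cyclin gene CCNE1 at −1.84 ± 0.22. In the mesenchymal list 12 of 23 lay below 0 and none above (12 and 1 adjusted over the list alone; camera adjusted p = 4e-04; 0.135 with an estimated correlation). NF-kB targets and cytokines lay below 0, 9 of 27 with 1 above (11 and 2 adjusted over the list alone; camera adjusted p = 0.000242; 0.116 with an estimated correlation). TNFAIP3 stood at −2.84 ± 0.19, and of 24 genes of ATF4 and amino acid stress 12 lay below 0 and 1 above (12 and 2 adjusted over the list alone; camera adjusted p = 0.000914; 0.273 with an estimated correlation). ATF3 stood at −2.50 ± 0.22.

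Under paclitaxel the difference between the lines was called for 2290 genes, 1325 above 0 and 965 below; with RLE factors it was 2272, 1043 above and 1229 below, and by DESeq2 2777, 1299 above and 1478 below, so the balance of directions moved with the scaling. IGFBP3, a growth factor binding protein, stood at 3.23 ± 0.71 (2.08 without H1975 control library 3), IFITM2 at 2.84 ± 0.31 and OASL at −2.63 ± 0.24. DNA repair genes lay above 0, 10 of 21 with 1 below (15 and 1 adjusted over the list alone; camera adjusted p = 0.00647; 0.834 with an estimated correlation). RAD51AP1 stood at 1.78 ± 0.45 and the exonuclease gene EXO1 at 1.48 ± 0.32. Of 25 cholesterol genes 7 lay below 0 and none above, also adjusted over the list alone (camera adjusted p = 0.00647; 0.874 with an estimated correlation). LSS stood at −1.80 ± 0.34 and HSD17B7 at −1.91 ± 0.34. FOXO targets lay above 0, 8 of 19 with 2 below (10 and 2 adjusted over the list alone; camera adjusted p = 0.0478; 0.834 with an estimated correlation). FBXO32 stood at 1.20 ± 0.18 (0.77 with the trend removed) and CITED2 at −1.46 ± 0.22. The count of 2290 fell to 1113 without H1975 control library 3, 1319 and 1297 without H1975 paclitaxel library 2 or 3, 1228 without PC9 control library 3, and 1479 and 1413 without PC9 paclitaxel library 1 or 2.

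Under the combination the difference between the lines was called for 2402 genes, 935 above 0 and 1467 below (2439 and 2317 without the 3 libraries that stood apart). The actin-bundling gene ESPN stood at 3.57 ± 0.29, SAA1 at 3.28 ± 0.31 and IFITM2 at 3.20 ± 0.31, and the semaphorin receptor gene PLXNA4 at −4.12 ± 0.40. G1-S genes lay below 0, 21 of 34 with none above (24 adjusted over the list alone), with a median of −1.10 (camera adjusted p = 2.61e-13), and the call held with an estimated correlation (adjusted p = 0.0317), RRM2 at −1.49 ± 0.16 and CDC25A at −2.29 ± 0.24. EGFR and MAPK targets lay below 0, 12 of 30 with none above (13 and 1 adjusted over the list alone; camera adjusted p = 0.000164; 0.243 with an estimated correlation). PHLDA1 stood at −2.80 ± 0.16, with HBEGF at −3.66 ± 0.24 and AREG at −2.54 ± 0.25. Ribosome biogenesis genes lay below 0, 12 of 27 with 1 above (13 and 1 adjusted over the list alone; camera adjusted p = 0.000195; 0.243 with an estimated correlation). NOP56 stood at −1.34 ± 0.18 and RRS1 at −1.65 ± 0.22. G2-M genes lay below 0, 12 of 30 with none above (15 adjusted over the list alone; camera adjusted p = 0.00607; 0.243 with an estimated correlation). AURKA stood at −1.21 ± 0.16 and KIF2C at −1.06 ± 0.16.

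Several genes with the largest fitted differences between the lines had far fewer reads in one of them, so raw counts over 12 libraries are given in place of a fitted value. Keratin and envelope genes had counts in PC9: KRT4 2906 against 8 in H1975, KRT6A 7123 against 8 and SPRR1A 2164 against 20. TDRD9 had 32 raw counts in PC9 and 11984 in H1975, SERPINA1, the gene of alpha-1 antitrypsin, 6 and 30206, G0S2, a lipase inhibitor gene, 731 and 17681, and CSF2, the gene of the cytokine GM-CSF, 163 and 4095.

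Across the 11778 genes tested in both lines, Pearson's r between the log2 fold changes of PC9 and H1975 was 0.387 under almonertinib (Spearman's rho 0.399), 0.101 under paclitaxel (0.0447) and 0.221 under the combination (0.154); it is a correlation across genes, which are not independent replicates. For paclitaxel it went from −0.0564 without H1975 paclitaxel library 1 to 0.338 without H1975 control library 3, and for almonertinib from 0.217 without H1975 almonertinib library 3 to 0.462 without its library 1. For the combination it went from 0.138 without H1975 control library 2 to 0.299 without control library 3. Among genes called in both lines under almonertinib, 118 rose in both (44.9 for independent lists), 53 fell in both (19.9) and 14 went opposite ways. Under the combination 135 rose in both (48.1), 52 fell in both (21.6) and 17 went opposite ways, and under paclitaxel 30 rose in both (14.1), 13 fell in both (6.64) and 7 went opposite ways.

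EGFR, DUSP6, CDKN1A, CCND1, BCL2L11, MKI67, TUBB and TUBA1B were followed in every comparison, whatever their change; the drug efflux pump gene ABCB1 had too few reads to be tested. EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628) fell by −0.65 ± 0.13 under almonertinib in PC9, from 675 ± 57.2 to 429 ± 76.7 CPM, and stood at 0.24 ± 0.13 under paclitaxel and −0.25 ± 0.13 under the combination (edgeR adjusted p = 0.126 and 0.116, but 0.0251 and 0.0192 with the repeat number as a block). CDKN1A, which encodes the cell cycle inhibitor p21, fell by −1.62 ± 0.15, −1.74 ± 0.15 and −1.57 ± 0.15 under almonertinib, paclitaxel and the combination in PC9. CCND1, the gene of cyclin D1, fell by −0.55 ± 0.09, −0.36 ± 0.09 and −0.62 ± 0.09, and BCL2L11, which encodes BIM, rose by 0.47 ± 0.11, 0.45 ± 0.10 and 1.14 ± 0.10 in that order. TUBA1B fell by −0.93 ± 0.11, −0.45 ± 0.11 and −1.17 ± 0.11, though under paclitaxel not with all 24 libraries in the fit (edgeR adjusted p = 0.0547). TUBB fell by −0.67 ± 0.11 under almonertinib and −0.57 ± 0.11 under the combination and stood at −0.19 ± 0.11 under paclitaxel (edgeR adjusted p = 0.163). MKI67, the proliferation marker gene, stood at −0.35 ± 0.15 under almonertinib and −0.35 ± 0.15 under the combination (edgeR adjusted p = 0.0624 and 0.0684), and with the repeat number as a block it was called in both (−0.37 and −0.36, edgeR adjusted p = 0.0118 and 0.0158). Under paclitaxel MKI67 rose by 0.39 ± 0.15 and DUSP6 fell by −0.36 ± 0.12, but the call of MKI67 ended without control library 2 or 3 or paclitaxel library 1 or 3 (0.35 to 0.40, edgeR adjusted p = 0.07 to 0.114). That of DUSP6 ended without control library 2 or 3 or paclitaxel library 2 or 3 (−0.35 to −0.24, edgeR adjusted p = 0.0505 to 0.142). With the length and GC trend removed TUBB stood at −0.38 and CCND1 at −0.23 under almonertinib, and BCL2L11 at 0.28, TUBA1B at −0.21 and MKI67 at 0.26 under paclitaxel, still called.

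Between the PC9 treatments, EGFR stood 0.40 ± 0.13 higher in the combination than under almonertinib, a call that ended without almonertinib library 2 or 3 or combination library 1 or 2 (0.27 to 0.42, edgeR adjusted p = 0.0626 to 0.142) or with the trend removed (0.15, 0.151), and BCL2L11 rose by 0.68 ± 0.10. CDKN1A (0.05 ± 0.15), CCND1 (−0.06 ± 0.09), MKI67 (0.00 ± 0.15), TUBB (0.11 ± 0.11) and TUBA1B (−0.25 ± 0.11) were not called. Against paclitaxel BCL2L11 rose by 0.69 ± 0.10, MKI67 fell by −0.74 ± 0.15, EGFR by −0.49 ± 0.13 and TUBA1B by −0.72 ± 0.11, while CDKN1A was not called (0.17 ± 0.15). CCND1 (−0.26 ± 0.09) lost its call without combination library 1 or 3 or paclitaxel library 1 (edgeR adjusted p = 0.105 to 0.125), and TUBB (−0.38 ± 0.11) without combination library 2 (0.0562). In the PC9 interaction CDKN1A was called at 1.79 ± 0.21 and DUSP6 at −1.02 ± 0.18, and the other 6 were not, though CCND1 was with the repeat number as a block (0.30, edgeR adjusted p = 0.0468). In H1975 CCND1 was at −0.65 ± 0.14 under almonertinib, a call lost without almonertinib library 2 or 3 or control library 1 or 2 (−0.67 to −0.60, edgeR adjusted p = 0.0677 to 0.131), and BCL2L11 at 0.68 ± 0.17 under the combination, a call lost without any 1 of the 6 libraries (0.64 to 0.72, edgeR adjusted p = 0.054 to 0.238) and with the repeat number as a block (edgeR adjusted p = 0.0756). No other of these genes was called in H1975: EGFR stood at −0.40 ± 0.20, −0.66 ± 0.20 and 0.11 ± 0.20 and DUSP6 at −0.76 ± 0.26, −0.30 ± 0.26 and −0.42 ± 0.26 under almonertinib, paclitaxel and the combination.

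Between the lines CDKN1A differed by −1.65 ± 0.29, −1.47 ± 0.29 and −1.11 ± 0.29 under almonertinib, paclitaxel and the combination, EGFR by 0.91 ± 0.24 under paclitaxel, DUSP6 by −2.50 ± 0.28 and TUBA1B by −0.96 ± 0.25 under the combination. The EGFR call ended without H1975 control library 3 (edgeR adjusted p = 0.0565). Under almonertinib DUSP6 differed by −0.80 ± 0.27 and under the combination MKI67 by −0.84 ± 0.29, calls lost without any 1 of 9 (edgeR adjusted p = 0.0566 to 0.129) and any 1 of 11 (0.06 to 0.135) of the 12 libraries compared; with the trend removed MKI67 differed by −0.55. Markers of leukocytes, fibroblasts, endothelium and neuroendocrine cells were nearly unmeasured, with 3 of 12, 2 of 10, 2 of 8 and 4 of 10 genes past the count filter in PC9, too few for a test as lists.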

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

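The tests of the interferon genes, the trend test of fewer calls in H1975 and the swap test were chosen only after the results were seen; the tests of depth, of PC9 cells, of the exchanged libraries and of other groupings were chosen before.

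The difference of each treatment effect between PC9 and H1975 was tested in one fit, and the genes and lists below differed by that test; line and dose changed together, so each is a difference of both. Under almonertinib 2216 genes differed. FN1 differed by −3.77, IL6 by −4.87, HBEGF by −3.85, AREG by −2.50, KLF4 by −2.73, PHLDA1 by −2.17, CCNE1 by −1.84, CDC25A by −1.93, TNFAIP3 by −2.84, ATF3 by −2.50, OASL by −3.17, CDKN1A by −1.65 and DUSP6 by −0.80 on the log2 scale, and IFITM2 by 3.22. The call of DUSP6 was lost under 12 of 19 settings, the removal of a length and GC trend among them (edgeR adjusted p = 0.0615). Median differences were −0.90 for mesenchymal genes, −0.87 for mitochondrially encoded genes, −0.71 for NF-kB targets and cytokines, −0.66 for G1-S genes, −0.55 for ATF4 and amino acid stress, −0.36 for Notch and differentiation, −0.32 for ER chaperones and 0.27 for NRF2 targets. None of these 8 list calls held with an estimated correlation (camera adjusted p = 0.116 to 0.643), and those of ER chaperones and Notch ended under the strict filter (both 0.0508). The mitochondrial share of counts itself was lower in PC9 almonertinib libraries, with a mean of 0.638%, than in H1975 almonertinib libraries (0.997%).

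Under paclitaxel 2290 genes differed between the lines. IGFBP3 differed by 3.23 (2.08 without H1975 control library 3, which also ended the EGFR call), IFITM2 by 2.84, RAD51AP1 by 1.78, EXO1 by 1.48, FBXO32 by 1.20 (0.77 with the trend removed) and EGFR by 0.91, and OASL by −2.63, HSD17B7 by −1.91, LSS by −1.80, CDKN1A by −1.47 and CITED2 by −1.46. Medians were 1.05 for DNA repair, 0.72 for FOXO targets and −0.54 for cholesterol synthesis. None of these 3 list calls held with an estimated correlation (camera adjusted p = 0.834 to 0.874), and that of FOXO targets ended with the block (0.0676).

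Under the combination 2402 genes differed between the lines. ESPN differed by 3.57, SAA1 by 3.28 and IFITM2 by 3.20, and PLXNA4 by −4.12, HBEGF by −3.66, PHLDA1 by −2.80, AREG by −2.54, DUSP6 by −2.50, CDC25A by −2.29, RRS1 by −1.65, RRM2 by −1.49, NOP56 by −1.34, AURKA by −1.21, CDKN1A by −1.11, KIF2C by −1.06, TUBA1B by −0.96 and MKI67 by −0.84 (a call lost under 12 of 19 settings). Medians were −1.10 for G1-S genes, −0.59 for ribosome biogenesis, −0.52 for MAPK targets, −0.50 for ERBB receptors and ligands, −0.49 for G2-M genes, −0.41 for NF-kB targets, −0.21 for Notch and 0.43 for FOXO targets. Of these 8 list calls that of G1-S genes held with an estimated correlation (camera adjusted p = 0.0317) and the others did not (0.243 to 0.563). The ERBB call also ended without a filter (0.0566) and with the strict filter (0.0852), and the Notch call under 4 settings (0.0566 to 0.125).

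Other groupings of the same libraries were counted for each comparison. They put libraries of different treatments in one group, which widens its spread, so they cannot exclude chance. For the differences between the lines and the interactions 100 groupings were used. Between the lines 1 of 100, the real one, reached 2216, 2290 and 2402 genes under almonertinib, paclitaxel and the combination. The highest others were 1162, 2270 and 106. For the PC9 interaction 1 of 100 reached 5826 (highest other 2740). Under paclitaxel the highest other came close, and leaving out 1 library took the real count to 1113. In the H1975 interaction 3 of 100 groupings reached 83 genes. The highest other called 407. These groupings mix all 4 treatments, so that count may hold treatment effects or another structure of the samples. For 3 libraries against 3 the 10 groupings are too few for a share under 0.05. In PC9 the real grouping called 7253, 7038 and 6489 genes against the control under almonertinib, paclitaxel and the combination, 5643 between combination and paclitaxel, with 0 by the edgeR test as the highest other in each, and 2570 between combination and almonertinib (highest other 839). In H1975 the real value was 79 for paclitaxel (highest other 0), 304 for the combination (highest other 1), 0 between combination and almonertinib (highest other 811, again a sign of such a structure) and 0 between combination and paclitaxel (highest other 0). Under almonertinib in H1975 the real grouping called 241 genes, and 2 of 10 groupings reached that; the other, which exchanges almonertinib library 1 with control library 3, called 5240, which points to a structure of these samples other than treatment.

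As a list, interferon genes were higher under each treatment than in the controls of both lines. In PC9 2, 4 and 2 of 38 fell under almonertinib, paclitaxel and the combination, and the list calls did not hold with an estimated correlation (camera adjusted p = 0.337, 0.826 and 0.429). There the tables argue against an offset of the controls alone, since the treated groups also differed among themselves (median of the list −0.77 between combination and almonertinib, SE 0.155), against a trend with transcript length and GC (median 1.64 after its removal) and against 1 control library (lowest median 1.26 without 1 control). In H1975 a trend (median 1.48 after removal) and 1 control library (lowest median 1.48) were argued against alike. Between combination and almonertinib no list member was called in H1975 (median −0.45, SE 0.0708, again over list members). An offset of the controls cannot be told apart from a response to each drug in either line. The interaction below 0 of these genes (median −1.85 in H1975) rests on the same 3 controls of each line and stays open with it. A response to the drugs stays open as a hypothesis in both lines.

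Fewer genes were called in H1975 than in PC9. Depth was argued against, since PC9 libraries thinned to the H1975 totals still called 6409 genes under the combination. A trend with length and GC was argued against as the whole cause, since after its removal H1975 called 1755 genes and PC9 7475, though it may be part of it: the coefficient of variation between repeats went from 0.191 to 0.121 in H1975 and from 0.111 to 0.0763 in PC9. Line and dose stay open and were not tested.

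H1975 almonertinib library 1 and control library 3 lay apart from their groups. Swapped labels were argued against, since on the interferon list almonertinib library 1 lay at 0.719 on a scale from the other controls (0) to the other almonertinib libraries (1), and control library 3 at 0.214. PC9 cells in almonertinib library 1 were argued against, since genes nearly absent from H1975 reached a median of 0.0393% of their PC9 level, with AKR1C2 at 0 against 1134 CPM and GPX2 at 0.359 against 767 CPM. A trend with transcript length and GC is a candidate explanation: its removal lowered the calls of the exchanged grouping from 5240 to 818 and raised those of the real one from 241 to 1057. What gave rise to the trend is open.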

How the results depend on the processing

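The fits with a length and GC trend removed, without 3 libraries that stood apart (H1975 almonertinib 1, H1975 paclitaxel 1 and PC9 almonertinib 3) and without the first of these in H1975 were chosen after the data were seen. Of 324 called values of named genes, 302 stayed called in the same direction under all settings that could test them, and 22 lost the call under at least 1. Folds that kept the call but moved by over 1.5 times stand beside their genes. The PC9 counts for almonertinib, paclitaxel, the combination (all against control) and the interaction stayed within 1.5 times of the main count under every setting. Leaving out 1 library gave 6420 to 8093, 5726 to 6418, 5353 to 5915 and 4910 to 7474. The genes moved more: with the trend removed 5872 of 7253, 4994 of 7038, 5935 of 6489 and 3850 of 5826 main calls remained. Other counts moved further as given next, and the cause was not tested.

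Between combination and almonertinib in PC9, 2570 became 918 with all 24 libraries in one fit, 1318 with only the 2 groups, 4184 without the 3 libraries, and 1274 to 4184 without 1 library. Between combination and paclitaxel in PC9, 5643 became 3734 with all 24 libraries. In H1975 with all 24 libraries the counts were 536 for almonertinib, 245 for paclitaxel, 1258 for the combination, 45 and 775 for the combination against almonertinib and paclitaxel, and 340 for the interaction. With only the 2 groups they were 46 for almonertinib, 1917 for the combination and 822 against paclitaxel. DESeq2 called 172 for paclitaxel, 699 for the combination, 41 and 481 for the combination against almonertinib and paclitaxel, and 248 for the interaction. With the trend removed they were 1057, 475 and 1755 for almonertinib, paclitaxel and the combination, 208 for combination against paclitaxel and 373 for the interaction. Without the 3 libraries they were 1783, 538 and 2439, then 2004 and 2359 for the combination against almonertinib and paclitaxel, and 1511 for the interaction. Without almonertinib library 1 they were 237 for paclitaxel, 1474 for the combination and 600 against paclitaxel. A term for the repeat as a block gave 202 for the combination and changed no call of a named gene in the 2 comparisons with correlated numbers beyond MKI67 and BCL2L11; in PC9 7 of 12 libraries and in H1975 4 of 12 correlated best with their own number. Combination against paclitaxel gave 56 with RLE factors, 54 without a filter and 3 with the strict filter. Without 1 library the H1975 counts ran from 99 to 906, 33 to 54 and 64 to 419 for almonertinib, paclitaxel and the combination, from 0 to 1101 and 0 to 424 for the combination against almonertinib and paclitaxel, and from 29 to 596 for the interaction.

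The counts that differed between the lines became 3903, 3496 and 4079 under almonertinib, paclitaxel and the combination with the trend removed, and 5323 and 4756 under paclitaxel and the combination without the 3 libraries; without 1 library the paclitaxel count ran from 1113 to 2975. The balance of directions moved with the totals, and the near-even balances in PC9 turned under some settings. With the trend removed, calls above and below 0 were 510 and 547, 210 and 265, and 787 and 968 in H1975 under almonertinib, paclitaxel and the combination, and 229 and 144 in the H1975 interaction. Without the 3 libraries they were 833 and 950 under almonertinib and 844 and 667 in the interaction, and with all 24 libraries 225 and 115 in the interaction. Between the lines they were 1707 and 1528 under almonertinib without the 3 libraries. In PC9 combination against almonertinib they were 655 and 263 with all 24 libraries and 1435 and 1966 with the trend removed.

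Pearson's r between the lines became 0.296 for the combination, 0.317 against almonertinib and 0.263 for the interaction with the trend removed, and 0.636 and 0.149 for the combination against almonertinib and paclitaxel over genes of at least 5 CPM.

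Of 171 list calls 17 held with an estimated correlation, the setting that ended the most. RLE factors ended 2, no filter 9, the strict filter 13, the block 4 and leaving out the 3 libraries 22. List calls were not retested with the trend removed, with DESeq2, with all 24 libraries or only the 2 groups, or without single libraries.

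Genes that were followed in every comparison and not called changed sign under some settings. With the trend removed, MKI67 stood at −0.30 and TUBB at −0.058 between combination and almonertinib in PC9, CDKN1A at −0.032 between combination and paclitaxel, and CCND1 at −0.0023, TUBB at −0.044 and TUBA1B at −0.14 in the PC9 interaction. In H1975, CDKN1A stood at −0.042 under almonertinib, EGFR at −0.19 under the combination, and CCND1 at −0.078 and −0.19 for the combination against almonertinib and paclitaxel. Between the lines MKI67 stood at 0.10 and TUBB at 0.25 under almonertinib, BCL2L11 at −0.012 under paclitaxel, and CCND1 at 0.23 and TUBB at 0.017 under the combination. Without the 3 libraries MKI67 stood at −0.21 between combination and almonertinib in PC9, and in H1975 CDKN1A at −0.34 under almonertinib, DUSP6 at 0.13 against paclitaxel, and CDKN1A at 0.093 and BCL2L11 at 0.13 in the interaction; between the lines TUBB stood at 0.15 under almonertinib and DUSP6 at 0.22 under paclitaxel. With RLE factors and with DESeq2 alike CDKN1A stood at −0.026 in H1975 almonertinib, BCL2L11 at 0.016 and 0.017 in the H1975 interaction and TUBB at −0.060 between the lines under paclitaxel. CDKN1A in H1975 almonertinib stood at −0.00925 without a filter, −0.021 with the block and −0.045 with only the 2 groups, and DUSP6 between the lines under paclitaxel at 0.018 with the strict filter.

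Without 1 library, CDKN1A ran from −0.11 to 0.29 and MKI67 from −0.21 to 0.14 between combination and almonertinib in PC9. In H1975, CDKN1A ran from −0.34 to 0.19 under almonertinib, DUSP6 from −0.26 to 0.13 for combination against paclitaxel, and CDKN1A from −0.40 to 0.13 and BCL2L11 from −0.12 to 0.15 in the interaction. Between the lines BCL2L11 ran from −0.041 to 0.10, MKI67 from −0.34 to 0.14 and TUBB from −0.31 to 0.26 under almonertinib, and DUSP6 from −0.27 to 0.19 and TUBB from −0.038 to 0.13 under paclitaxel. Depth limits the genes near the filter, where fold changes rest on few counts.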

Other observations

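The test of a shared response was chosen before its result was seen; the chromosome 19 segment and the rule that labels its test were settled after.

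Some other lists in PC9 under almonertinib went both ways and were not called by camera. Of 25 p53 targets 6 rose and 9 fell (7 and 9 adjusted over the list alone), TP53INP1, from 19 raw counts over the 3 controls, by 3.61 ± 0.37 and AEN by −2.10 ± 0.09. Of 21 DNA repair genes 6 rose and 8 fell, ATM by 1.93 ± 0.37 and CHEK2 by −2.01 ± 0.11. Of 27 hypoxia genes 10 rose and 11 fell, P4HA1 by 1.37 ± 0.18 and VEGFA by −1.36 ± 0.09. Of 29 lysosome genes 5 rose and 11 fell, ATG5 by 1.05 ± 0.19 (0.55 with a length and GC trend removed) and CTSL by −1.53 ± 0.10. Of 16 heat shock genes 4 rose and 4 fell, HSP90AA1 by 1.09 ± 0.22 and FKBP4 by −1.06 ± 0.10, and of 12 other receptor kinases 2 rose and 5 fell, AXL by −1.30 ± 0.09 and FGFR3 by 0.84 ± 0.10. Of 11 transporter genes 6 rose and 1 fell, ABCC4 by 1.52 ± 0.17. Of 4 measured neuroendocrine markers, too few for camera, UCHL1 fell by −0.48 ± 0.12 (−0.18 with the trend removed) and none rose.

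The log2 fold changes of almonertinib and paclitaxel were alike across genes in each line, and the drugs may share a response. Both were compared with the same 3 controls, which alone makes them alike, so the covariance was set against 20 simulated data sets with no response. It was 0.466 in PC9 (0.0210 to 0.0240 simulated) and 0.0957 in H1975 (0.0334 to 0.0377 simulated), more than shared controls gave in the simulation. In PC9 2251 genes rose under both drugs (998 for independent lists), 2072 fell under both (996) and 361 went opposite ways, and in H1975 54 rose under both (0.744) and 14 fell under both (0.144). Genes are not independent replicates, and 3 controls are too few to split, so an offset of the control libraries may be part of this excess.

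On chromosome 19, from 19785839 to 23395560 (GRCh38), 24 zinc finger genes had at least 500 raw counts in a line, and in PC9 22 of them had at most 60, with 33 counts in all against 45612 in H1975. A run of 11 neighbouring genes nearly absent from PC9 was longer than the longest run of 4 in 10000 shuffles. Loss of the whole segment in PC9 is a candidate explanation that cannot be told apart from silencing: 0 of its genes reached 500 counts in PC9, but the segment was chosen for its low counts, so that decides nothing. The exceptions were ZNF430 with 96 and ZNF431 with 433 raw counts in PC9, against 1479 and 2307 in H1975; these may be reads of related zinc finger genes or expression. No DNA was measured.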
